A study of Mus musculus with 2 samples.

How the data were processed

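DNase-seq maps open chromatin by sequencing the ends of DNA released where the enzyme DNase I cleaves it. It was run here on liver of mouse embryos at day 13.5, when the liver is a main site of red cell formation. Per the labels, the mice are of strain C57BL/6N,129 and carry an LCR deletion and a HET globin mutation. The labels do not spell out LCR; it is read here as the locus control region, the distant enhancer cluster of the beta-globin genes. The extent of the deletion, the meaning of HET globin mutation and the genotype of each embryo are not given in the sources used here. The 2 libraries form 1 group, biological replicates 1 and 2, from different biosamples under the same donor identifier. There was no control group, and sex was recorded as not collected.

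For each library the authors derived 4 tables from its own filtered alignments to mm10 (GRCm38): a longer and a shorter peak list, footprints, and a false discovery rate of the cleavage rate along the genome. Peaks were made per library, not pooled. The peak caller, its version and its threshold are not given in the sources used here. The value of each peak is the authors' depth-normalised cleavage signal at that peak. These values are whole multiples of 1 step per library, 0.0123 in replicate 1 and 0.0139 in replicate 2, with a largest departure of 0.00407 and 0.00489 of a step. If 1 step is 1 read on a scale of 1e6 reads, the depth was 81.2 and 72.1 times 1e6 reads; that reading is an assumption. The 95% Poisson intervals of single peak values rest on it and cover counting error only. How values compare between libraries is not given in the sources used here. For that reason each library's values are given side by side. Ratios between libraries are also given after a running median over shared peaks of like height, ranked by mean log value, was taken off (the excess ratio), which removes any factor per library. The deposited false discovery rate is the adjusted p-value (q-value type) in the files and is given only for stretches under 0.05. It was used to describe what the lists hold: the lowest rate in a peak reached 0.0498 at most in the longer lists, and 0.000996 and 0.000993 at most in the shorter lists. The deposited footprint score is another constant, 0.01, so only footprint positions were used. The p, q and summit columns of the peak lists hold constants and were not used.

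Chromosomes 1 to 19, X and Y were used, with the longer list as the main one. Transcription starts and gene bodies came from GENCODE vM21 protein-coding genes. Peaks that overlapped by at least 1 base were shared. Overlap, nearness to transcription starts within 1000 bases, and footprint sharing were each set against 100 shuffles, one-sided. Shuffles stayed within the chromosome, or within the peaks for footprints. A promoter was open in both libraries when each had a peak within 1000 bases of a start of the gene. Distal peaks were shared peaks over 1000 bases from any start, those of non-coding genes included, and within 50000 bases of the gene. Both counts were compared, for 16 gene lists, with 10000 random lists of equal size in 2-sided permutation tests. Random lists for distal peaks were matched on gene length. The adjusted p-values are Benjamini-Hochberg values over the lists. They describe these 2 libraries, since genes are not replicates. Of 179 list genes 178 had a match in the annotation. The lists are beta-globin, alpha-globin, erythroid regulators, erythroid membrane and heme, hepatoblast, mature hepatocyte, blood stem and progenitor, megakaryocyte, macrophage and myeloid, lymphoid, endothelial, stellate and mesenchymal, cholangiocyte, neuronal, muscle and housekeeping. Erythroid regulators such as Lmo2, Lyl1, Tal1, Gfi1b and Ikzf1 also act in blood progenitors, and Gata1, Nfe2 and Zfpm1 in megakaryocytes. Consensus matches of 22 transcription factor motifs were counted in footprints widened by 5 bases on each side. They were compared with windows of equal length shifted by 100 bases within the same peak by Fisher's exact test, with adjustment over the motifs. An odds ratio is given only where a motif had at least 10 matches in footprints and windows together in each library.

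All genes of the globin lists and all peaks of the globin loci are named. From the other lists, the text names up to 3 genes with the highest promoter peaks and up to 3 without a promoter peak in either library, first in the alphabet. It also names the 10 genes with the most shared distal peaks and the 5 highest peaks. Genes named outside this rule were chosen after their values were seen. The lists, motifs, tests, naming rule and all alternatives but 2 were set before the data were examined. The alternatives were the shorter list, the upper 50% of peaks by value, other distances and overlaps, and random lists matched on promoter CpG content or on neighbouring genes. They also included narrower footprint choices and leaving out each replicate. The 2 chosen after seeing the data were runs of neighbouring genes and leaving out the gene of a list with the most distal peaks. The calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, pysam 0.24.0, bedtools 2.31.1 and samtools 1.23.1, with figures in matplotlib 3.10.9. The list test was tested on simulated data: it called 97.5% of 40 lists planted at 90% open genes and 4.5% of 200 unchanged lists at p under 0.05. The matched form called 2.0% of lists that differed only in the matched property, where the unmatched form called 74.5%. The library ratio at like height returned -1.09 for a planted log2 change of -1, and the motif comparison 2.69 for a planted odds ratio of 3.06.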

Results

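The data are 2 DNase-seq libraries of mouse liver at embryonic day 13.5, replicates 1 and 2 of 1 group with an LCR deletion and a HET globin mutation. Replicate 1 had 47198 peaks over 9.65 Mb and replicate 2 had 36523 peaks over 8.72 Mb. The shorter lists held 29534 and 23395 peaks. The median peak value, the authors' signal, was 1.232 in replicate 1 and 1.248 in replicate 2. The 99th percentile of values was 19.3 and 8.68. Stretches with a listed false discovery rate covered 16.2 and 14.5 Mb. With 1 step of the value read as 1 read, a median peak held 100 reads in replicate 1 and 90 in replicate 2.

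The 5 sites with the highest mean rank of value over both libraries included 3 within a gene. The first of the 5, on chromosome 17 from 39846781 to 39846900, lay 103619 bases from Esp38, with values of 80.6 and 160.4 in replicates 1 and 2. Next came a site in Lars2, a mitochondrial leucyl-tRNA synthetase, on chromosome 9 from 123461901 to 123462100, with 42.4 and 86.9. A site in Zc3h7a on chromosome 16 from 11144171 to 11144320 had 36.9 and 92.2. A site 7303 bases from Tra2a on chromosome 6 from 49236421 to 49236620 had 40.05 and 67.0, and one in Dynlt1b on chromosome 17 from 6430021 to 6430200 had 57.3 and 26.7. Of the peaks of replicate 1, 64.4% overlapped a peak of replicate 2, and 82.3% did so the other way. Shuffled peaks overlapped in 0.660% and 0.810%, and in 0.771% and 0.945% at most (one-sided permutation p = 0.0099, the smallest that 100 shuffles can give). Across 26687 peaks that overlapped 1 to 1, values ranked alike, with a Spearman correlation of 0.942 (95% interval 0.941 to 0.943). This correlation is across peaks, which are not independent replicates. The value was lower in replicate 2 for 84.3% of these peaks, with a median log2 ratio of replicate 2 to replicate 1 of -0.50. By decile of the mean log value of both libraries, the median ratio ran from -0.09 in the lowest to -1.11 in the highest. Since the normalisation between libraries is unknown, this says how unequal the ratios were, not which library had more open chromatin. Of the 5 highest sites, those in or nearest to Esp38, Lars2, Zc3h7a and Tra2a were higher in replicate 2, unlike most peaks. Their log2 ratios were 0.99, 1.04, 1.32 and 0.74, and the Dynlt1b site had -1.10. The reason was not tested, so the high rank of these sites is not read as the most open chromatin.

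**Figure D1:**
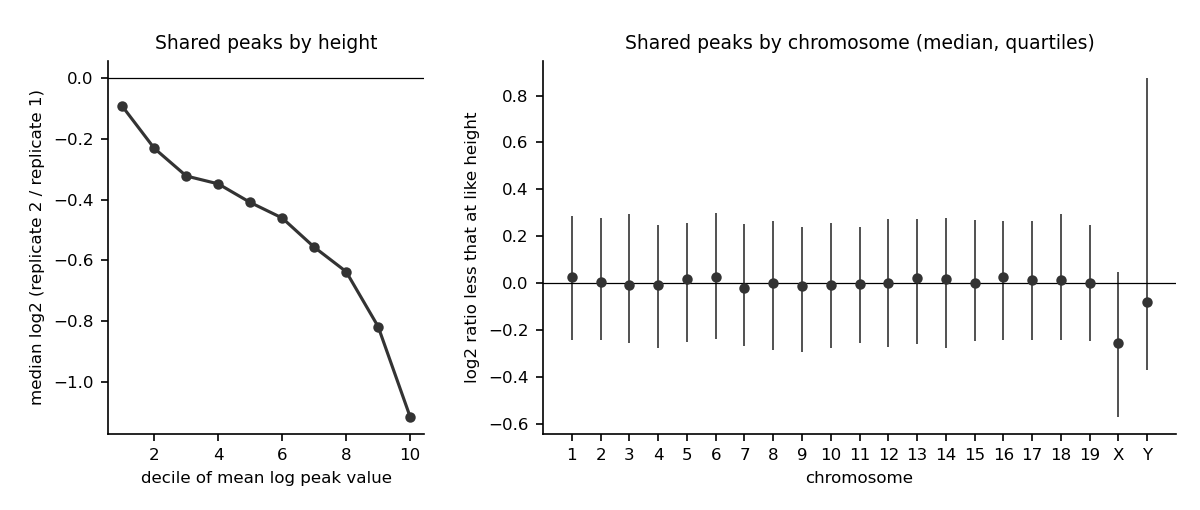
Left, the median log2 ratio of the peak value (replicate 2 to replicate 1) by decile of the mean log value of both libraries, from -0.09 to -1.11; right, the log2 ratio after the median at like height was taken off, by chromosome, with points as medians and lines as quartiles. Autosomal medians lie between -0.02 and 0.03, the X median over 698 peaks is -0.25, and Y has only 13 peaks.

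Peaks with no overlap in the other library numbered 16816 in replicate 1 and 6480 in replicate 2. Their median values were 0.653 and 0.596, against 1.98 and 1.51 for shared peaks. Away from transcription starts, 11458 peaks were seen in replicate 1 alone and 3356 in replicate 2 alone, a log2 ratio of -1.77. Within 50000 bases of the beta-globin genes, summed over the genes, these counts were 18 and 0, and for the alpha-globin genes 5 and 0. A peak near several genes of a list was counted for each of them. The globin genes lie close together, so their counts stand for fewer sites. The whole beta-globin locus had 9 peaks in replicate 1 and 4 in replicate 2. Around erythroid regulators the counts were 35 and 4 (log2 ratio -3.13), around erythroid membrane and heme genes 35 and 13 (-1.43), and around hepatoblast genes 23 and 5 (-2.20). Around macrophage and myeloid genes they were 14 and 1 (-3.81), around mature hepatocyte genes 10 and 2 and around neuronal genes 15 and 3 (-2.32 each), and around lymphoid genes 6 and 7 (0.22). Endothelial genes had 9 and 2 (-2.17) and cholangiocyte genes 4 and 0. Above the ratio of -1.77 also lay stellate (9 and 3, -1.58), progenitor (24 and 9, -1.42) and megakaryocyte genes (6 and 3, -1.0). Housekeeping (9 and 6, -0.58) and muscle genes (5 and 4, -0.32) lay above it too. These counts compare 1 library with 1 library, so no test was made.

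Peaks gathered at gene starts. In replicate 1, 44.2% of peaks lay within 1000 bases of a protein-coding start (exact binomial 95% interval 43.8 to 44.7), and in replicate 2 the share was 52.6% (52.1 to 53.1). The mean was 48.4% ± 5.94 (SD, n = 2). Shuffled peaks gave 2.83% and 2.86% (one-sided permutation p = 0.0099, the smallest possible, in each library). Peaks near starts were higher, with median values of 2.19 and 2.00 against 0.936 and 0.929 for the others.

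Promoters of erythroid regulators, of erythroid membrane and heme genes and of housekeeping genes were open more often than those of random lists. Those of hepatoblast, mature hepatocyte, myeloid, megakaryocyte, endothelial and cholangiocyte genes were open less often, but only the erythroid lists passed when random lists were matched on promoter CpG content. Of 21884 protein-coding genes, 12527 had a promoter peak in replicate 1, 11837 in replicate 2 and 11569 (52.9%) in both. Among erythroid regulators 11 of 12 promoters were open in both libraries. The highest belonged to Zfpm1 (FOG1, the cofactor of GATA1; values 26.8 and 12.2 in replicates 1 and 2), Nfe2 (a subunit of a globin gene activator; 17.9 and 6.72) and Lyl1 (a blood transcription factor; 17.7 and 7.17). Erythroid membrane and heme genes were open in 17 of 19 cases. Epb41, which encodes a protein of the red cell membrane skeleton, had 33.0 and 12.9, the transferrin receptor gene Tfrc 18.1 and 7.46, and the erythropoietin receptor gene Epor 15.3 and 6.39. The mitochondrial iron carrier gene Slc25a37 had no promoter peak. All 12 housekeeping promoters were open, among them those of the ribosomal protein gene Rplp0 (22.4 and 10.8), the actin gene Actb (22.3 and 10.5) and the cyclophilin gene Ppia (16.8 and 8.89).

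Few promoters of liver cell genes had a peak in both libraries. None of the 14 mature hepatocyte promoters, such as those of Cps1 (urea cycle), Cyp1a2 and Cyp2e1 (drug metabolism), was open in either library. Of the hepatoblast genes 4 of 18 were open in both libraries. The liver factor genes Foxa3 (9.41 and 4.33) and Cebpa (3.06 and 2.16) and the transferrin gene Trf (1.37 and 0.790) had peaks, and the genes of alpha-fetoprotein (Afp), albumin (Alb) and apolipoprotein A-II (Apoa2) did not. In replicate 1, 10 hepatoblast promoters had a peak, those 4 included. Blood stem and progenitor genes were open in 7 of 11 cases, including Runx1 (5.66 and 4.35), the stem cell factor receptor gene Kit (3.72 and 2.41) and Myb (4.005 and 2.19), but not Fli1 or Gata2. The megakaryocyte list had 1 of 10, the integrin gene Itgb3 (1.01 and 0.846), while the platelet genes Gp6, Gp9 and Pf4 had none. None of the 13 macrophage and myeloid promoters was open in both libraries, Adgre1 (F4/80), C1qa and Cd163 among them. The endothelial list had 1 of 10, the VEGF receptor gene Kdr (0.887 and 0.693), while Cdh5, Emcn and Lyve1 had none. None of the 6 cholangiocyte genes, Epcam and Krt19 among them, was open in both.

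Against random lists, adjusted permutation p-values were 0.0329 for erythroid regulators, 0.0072 for erythroid membrane and heme genes and 0.00533 for housekeeping genes, all above the mean of random lists. Below it lay mature hepatocyte and myeloid genes (0.0016 each, from a raw p of 0.0002, the smallest the permutations can give), megakaryocyte and endothelial genes (0.0329 each), hepatoblast genes (0.0356) and cholangiocyte genes (0.038). The other lists did not pass the permutation test. Lymphoid genes had 2 of 10 open, Pax5 (2.96 and 2.07) and Ebf1 (2.49 and 1.39), but not Bcl11b or Cd3e (adjusted permutation p = 0.104). Stellate and mesenchymal genes had 3 of 11, the collagen gene Col1a1 (2.42 and 1.40), Reln (1.33 and 1.33) and Lhx2 (1.10 and 1.01), but not Acta2, Col1a2 or Col3a1 (permutation 0.198). Neuronal genes had 3 of 12, Snap25 (1.11 and 1.12), Syn1 (1.05 and 0.776) and Rbfox3 (1.10 and 0.499), but not Gad1, Gad2 or Gfap (permutation 0.136). Muscle genes had 2 of 10, Mylpf (6.37 and 2.91) and Actn2 (1.37 and 0.790), but not Acta1, Ckm or Myh1 (permutation 0.104). The beta-globin and alpha-globin lists, each with 2 of 5, had 0.893, and the progenitor list 0.773. With random lists matched on promoter CpG content, the erythroid regulator and the erythroid membrane and heme lists passed (permutation 0.0016 each) and the housekeeping list did not (0.18). The hepatoblast call was lost with replicate 1 alone (permutation p = 1.0), the cholangiocyte call with replicate 2 alone (0.175), the megakaryocyte call with either alone (0.223 and 0.0998), and that of erythroid regulators within 2500 bases of a start (0.0523).

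**Figure D2:**
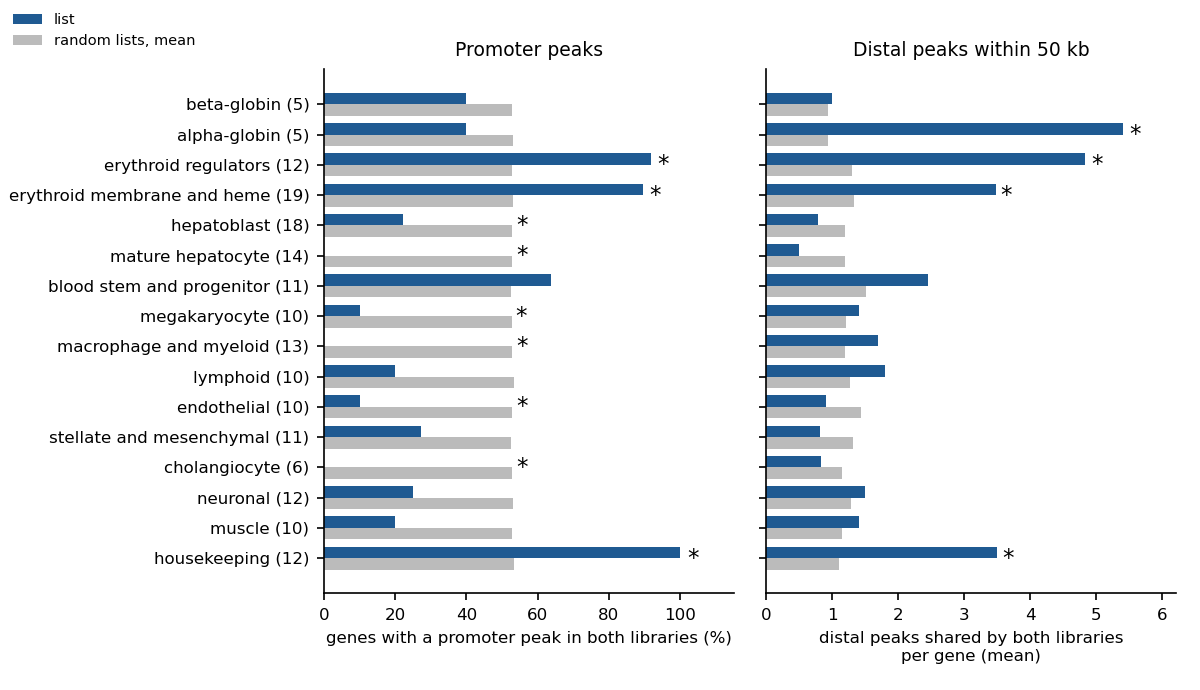
Left, the percent of genes in each list (number of genes in parentheses) with a promoter peak in both libraries, and right, the mean number of shared distal peaks per gene; blue is the list, grey the mean of the random lists, and stars mark lists with an adjusted permutation p under 0.05. Promoters were open in 91.7% of erythroid regulators and 0 of the mature hepatocyte genes, and the alpha-globin list had 5.4 distal peaks per gene.

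Distal open sites were more frequent near erythroid, alpha-globin and housekeeping genes than near the genes of random lists. Genes had a mean of 1.26 shared distal peaks within 50000 bases. Erythroid regulators had 4.83 per gene, 3.73-fold the mean of the random lists, and erythroid membrane and heme genes had 3.47, which was 2.63-fold. Of the 66 peaks of the latter list, 26 belonged to Slc4a1; without it the other 18 genes had 2.22, which was 2.10-fold the mean of random lists without their own highest gene (permutation p = 0.0264 after adjustment, a comparison chosen after seeing the data). Housekeeping genes had 3.5 (3.20-fold). The alpha-globin genes had 5.4 (5.76-fold) and the beta-globin genes 1.0 (1.08-fold); with replicate 1 used alone the beta-globin mean was 4.6 against 1.57 in random lists (permutation p = 0.145). The anion exchanger gene of red cells, Slc4a1, had 26 distal peaks, its neighbours Rundc3a and Ubtf 27 and 21, and the corepressor-associated gene Gse1 31. Other genes with many were Fgfr2 (26), Btn1a1 (24), Abt1 (23), Gm21887 (21), Mid1 (21) and Gm20388 (100). Gm20388 (chromosome 8, 119910841 to 124345722) and Fgfr2 (chromosome 7, 130162451 to 133123350) are annotated over long spans that hold other genes. Gse1 lies within the span of Gm20388. Mid1 and Gm21887 on X, and Btn1a1 and Abt1 on chromosome 13, lie within 50000 bases of each other. A peak can thus count for both genes of such a pair.

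The adjusted permutation p-values were 0.0032 for erythroid regulators (from the smallest raw p, 0.0002), 0.0128 for erythroid membrane and heme genes, 0.00853 for alpha-globin and 0.00853 for housekeeping genes. No other list passed in the permutation test, and the beta-globin list had 0.859. The mean was 0.778 for hepatoblast, 0.5 for mature hepatocyte, 2.45 for progenitor, 1.4 for megakaryocyte and 1.69 for myeloid genes. It was 1.8 for lymphoid, 0.9 for endothelial, 0.818 for stellate, 0.833 for cholangiocyte, 1.5 for neuronal and 1.4 for muscle genes. The alpha-globin genes share their neighbourhood, so they were also compared with all 21800 runs of 5 neighbouring genes, a comparison chosen after seeing the data. Of these, 362 runs (1.66%) were as high (2-sided exact test over all runs, p = 0.0332, not adjusted over the lists). The runs overlap and are not independent. The alpha-globin call was lost with replicate 1 alone (permutation 0.08), with the shorter list (0.115) and within 20000 bases (0.232), the housekeeping call with replicate 1 alone (0.11), and the erythroid membrane and heme call with the upper 50% of peaks (0.156).

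At the beta-globin locus, chromosome 7 from 103791822 to 103879442, replicate 1 had 9 peaks and replicate 2 had 4. The adult genes were open in both libraries: the peak at the start of Hbb-bt (103813841 to 103814060) had 3.88 and 1.54, and that at Hbb-bs (103827961 to 103828100) had 4.65 and 1.91. A peak in Hbb-bs from 103826601 to 103826780 had 1.45 and 0.693. The embryonic gene Hbb-y had 0.764 at its start in replicate 1 (103853238 to 103853365) and no peak in replicate 2, and the promoters of Hbb-bh1 and Hbb-bh2 had none. A peak from 103844701 to 103844920, near Hbb-bh1, had 1.18 in replicate 1 alone.

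The stretch upstream of Hbb-y, 103853217 to 103879442, holds the locus control region in the reference genome. It had 5 peaks in replicate 1, the one at the start of Hbb-y included, and 1 in replicate 2. The highest, from 103861041 to 103861200, had 8.75 (8.12 to 9.42) in replicate 1 and 2.05 (1.73 to 2.41) in replicate 2. These values lie at percentiles 91.99 and 68.3 of all peaks of the library. Their log2 ratio was -2.09, where 1838 shared peaks of like value in replicate 1 had a median of -0.87 and none was lower. In replicate 1 footprints in or next to this peak matched GATA, NFE2 with AP-1, and KLF patterns, and in replicate 2 the footprint matched NFE2 with AP-1. Peaks from 103859201 to 103859340 (1.86), 103865781 to 103865980 (1.77) and 103870781 to 103870980 (1.68) were called in replicate 1 alone. There was no unedited control, so no test of the genotype was made, and none of these values separates the alleles.

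At the alpha-globin locus with Nprl3, chromosome 11 from 32225628 to 32300873, replicate 1 had 11 peaks and replicate 2 had 9. The theta-globin genes Hbq1b (32286841 to 32287060) and Hbq1a (32299941 to 32300160) had promoter peaks of 6.53 and 4.55, and of 4.03 and 2.88. The promoter of Nprl3 (32267541 to 32267760) had 9.11 and 7.24, and a peak at the start of Mpg (32226381 to 32226600) had 6.89 and 4.13. Hba-x, Hba-a1 and Hba-a2 had no promoter peak in either library. Within 1000 bases of the Hba-a1 start, 72.9% of the 36-base words recur at Hba-a2; the share was 35.2% for Hbb-bt in Hbb-bs and 34.2% for Hbq1b in Hbq1a. How reads with several matches were treated is not given in the sources used here, so a missing peak at Hba-a1 or Hba-a2 does not show a closed promoter.

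The introns of Nprl3 hold known enhancers of the alpha-globin genes. There, the peak from 32245681 to 32245989 had 6.94 and 2.18 with a GATA-E-box footprint in replicate 1, the one from 32238546 to 32238760 had 3.87 and 2.27, and that from 32256161 to 32256420 had 3.41 and 1.79. The peak from 32250941 to 32251160 had 5.41 (4.92 to 5.94) in replicate 1 and was not called in replicate 2. Between the genes, peaks from 32269061 to 32269260 had 3.72 and 2.16, from 32285071 to 32285249 had 6.46 and 2.95, and from 32285514 to 32285626 had 2.03 in replicate 1 alone.

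**Figure D3:**
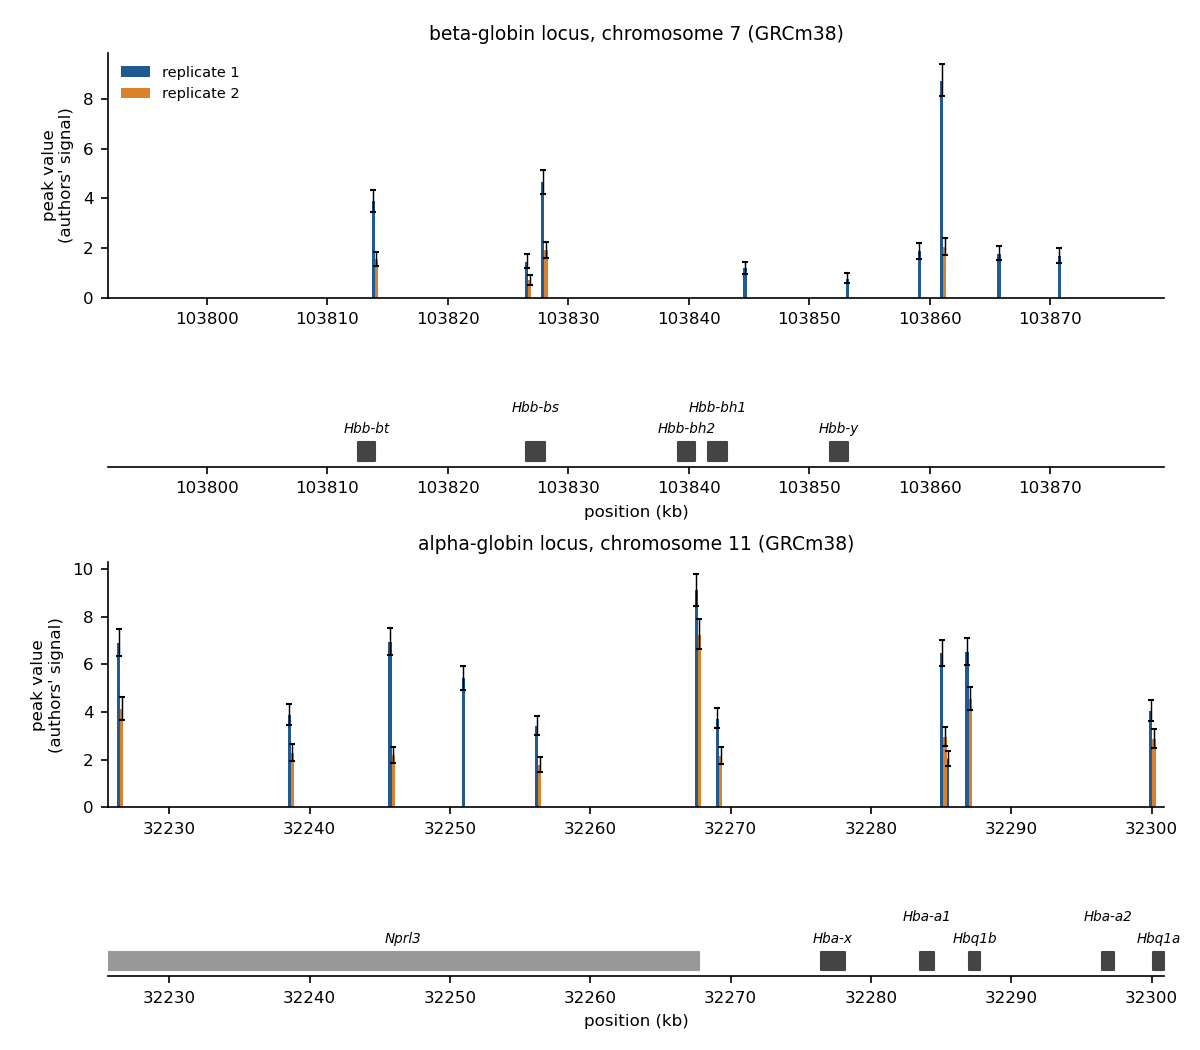
Peak values (the authors' signal) along the beta-globin and alpha-globin loci in replicate 1 (blue) and replicate 2 (orange), drawn at the peak position with a fixed bar width and side by side; error bars are 95% Poisson intervals with 1 step read as 1 read, and boxes are genes. The highest peak upstream of Hbb-y has 8.75 and 2.05, and the Nprl3 promoter 9.11 and 7.24.

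Footprints are short protected stretches within open sites, where a bound protein can shield DNA from DNase I. They matched the patterns of CTCF, the insulator protein, most strongly, with odds ratios against windows in the same peaks of 42.7 (22.4 to 81.4) in replicate 1 and 110 (38.2 to 315) in replicate 2. Patterns of NRF1, a factor of mitochondrial genes, had 17.4 and 23.4. The patterns of NFE2 and KLF had 6.01 and 7.29, and 4.21 (3.88 to 4.56) and 3.50 (3.26 to 3.75). SP had 6.43 and 5.04, ETS 1.55 and 1.68, NEUROD 1.75 and 1.42, and AP-1 1.36 and 1.33. NEUROD, MEF2 and P53 were set beforehand as patterns of factors not typical of this tissue. A raised ratio, as for NEUROD, therefore does not by itself name the factor bound. FOXA, a liver factor, was matched less often in footprints than in the windows, with 0.312 and 0.469. The windows were not matched to the footprints on base composition. Only footprints with such a window in the same peak were compared, 46388 in replicate 1 and 47712 in replicate 2. GATA, the pattern of main red cell regulators, had 1.04 (0.962 to 1.13) and 0.873 (0.788 to 0.967), with an adjusted p of 0.425 and 0.0194, and GATA-E-box had 2.45 and 1.40.

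All of these but GATA and GATA-E-box passed Fisher's exact test in both libraries, in the same direction. The higher adjusted p of the 2 libraries was 9.13e-08 for NFE2, 0.0325 for AP-1, 0.0102 for NEUROD and 0.000536 for FOXA. For GATA-E-box it was 0.00302 in replicate 1 and 0.446 in replicate 2. The patterns CEBP, NFY, MEF2, SRF, RUNX, PU.1 and P53 did not pass in both, and HNF1, HNF4, NFI and RFX had fewer than 10 matches in a library. Away from transcription starts ETS and FOXA no longer passed, with adjusted p of 0.0913 and 0.143. AP-1 did not pass without widening (0.290) or with footprints shared by both libraries (0.522). There were 123897 footprints in replicate 1 and 94430 in replicate 2, of which 84.96% and 86.5% lay in peaks (mean 85.7% ± 1.08, SD, n = 2), with 2.297 and 2.316 per peak. Of those in peaks, 34.1% and 48.1% were shared, against 11.2% and 14.6% in shuffles (one-sided permutation p = 0.0099, the smallest possible).

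**Figure D4:**
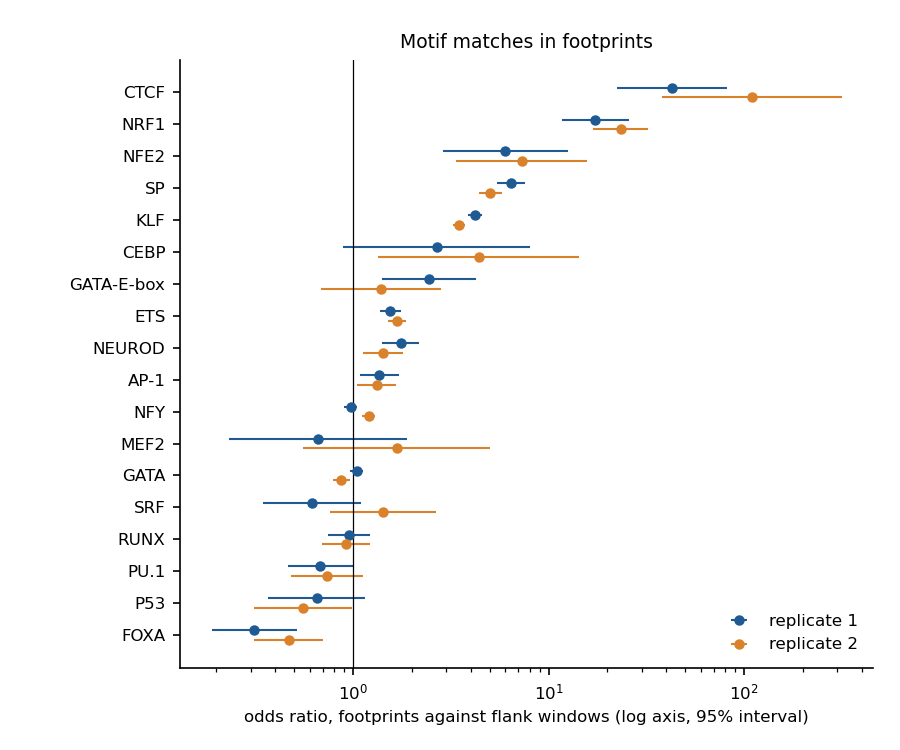
Odds ratios (log axis) of motif matches in footprints against windows in the same peaks, with 95% intervals, for replicate 1 (blue) and replicate 2 (orange). CTCF has 42.7 and 110, and FOXA 0.312 and 0.469.

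Of 4 Y-linked genes, 3 had a promoter peak in both libraries. Eif2s3y had promoter values of 0.567 and 1.43, Uty 0.333 and 1.07 and Ddx3y 0.505 and 1.05 in replicates 1 and 2, and Kdm5d had 0.596 in replicate 2 alone. The start of Xist, the RNA gene that silences an X chromosome in female cells, had a peak of 1.04 (103483141 to 103483340) in replicate 1 and none in replicate 2. X held 3.04% (exact binomial 95% interval 2.89 to 3.20) and 2.94% (2.77 to 3.12) of peaks, and Y held 28 and 34 peaks. The interval of the X share in each library includes the share of the other, and no test was made with 1 library against 1.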

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

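Of 393 values of 61 results under an alternative, 300 kept their direction and their side of the threshold or moved by less than a set margin. The margin was an interval around the main value, the SD of the 2 libraries or, for counts, a fixed ratio. Each of 2 replicates always lies within their SD of the mean. For means such as the share near starts, leaving out a replicate was thus no test. Another 26 calls were lost and 10 gained in the same direction. The direction changed for 28 values, of which 1 (NFY) gained a call, and 29 values without a test moved. The comparisons with runs of neighbouring genes and without the gene with the most distal peaks were chosen only after the result was seen. Unless said otherwise the cause was not tested. No paired analysis was possible because there is only 1 group. Motif values below are mean log2 odds ratios of the 2 libraries, and p-values are adjusted, except in the comparison with runs of neighbouring genes.

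With the shorter list, which holds fewer peaks by construction, the mean number of peaks was 26464.5, overlap was 70.2% of replicate 1 and 87.6% of replicate 2, and peaks in 1 library only were 8805 and 2911. The Spearman correlation was 0.9397, the share near starts 60.4%, the footprint share in peaks 71.0%, the X share 2.82% and the Y peaks 14 on average. Open promoters numbered 4 for progenitor genes (direction reversed), 0 for cholangiocyte genes (permutation p = 0.0672, call lost) and 1 for stellate genes (permutation p = 0.0388, call gained). Alpha-globin distal peaks fell to 2.6 per gene (permutation p = 0.115, call lost).

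With the upper 50% of peaks by value, again fewer by construction, the mean number was 20930, overlap 74.2% and 94.6%, and peaks in 1 library only 6083 and 986. The Spearman correlation was 0.913, the share near starts 64.9%, the footprint share 67.2%, the X share 1.956% and the Y peaks 9 on average. The cholangiocyte call was lost at 0 open promoters (permutation p = 0.0846), and the neuronal list passed at 0 (permutation p = 0.00512). The erythroid membrane and heme list had 1.37 distal peaks per gene (permutation p = 0.156, call lost).

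A reciprocal overlap of 50% gave overlaps of 50.2% and 65.0%, and a correlation of 0.945. Peaks in 1 library only then numbered 23491 in replicate 1 and 12790 in replicate 2. Pearson's correlation of log10 values was 0.949. Footprints wholly in a peak were 84.3%. Within 500 bases of a start lay 41.9% of peaks.

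With random lists matched on promoter CpG content, the calls for cholangiocyte (0 genes), endothelial (1), hepatoblast (4), housekeeping (12), myeloid (0), mature hepatocyte (0) and megakaryocyte genes (1) were lost, with permutation p from 0.112 to 0.443. The beta-globin and alpha-globin lists, with 2 genes each, then lay above the random mean but did not pass. Within 2500 bases of a start the calls for endothelial (2), hepatoblast (6), megakaryocyte (2) and erythroid regulator genes (11, permutation p = 0.0523) were lost. Alpha-globin (3) and neuronal genes (7) changed side of the random mean without passing in either case.

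For distal peaks, lists matched on neighbouring genes turned the direction of beta-globin (1.0) and muscle (1.4) genes, and runs of 5 neighbouring genes that of beta-globin (1.0); none passed. Within 20000 bases the alpha-globin call was lost at 1.6 (permutation p = 0.232), and beta-globin (0.4), myeloid (0.462) and muscle (0.5) genes changed direction without passing.

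Among motifs, windows at 50 bases gave GATA -0.37 and PU.1 -0.90, both now passing below 0, and turned RUNX (0.031) and SRF (0.16). Away from starts ETS (0.58) and FOXA (-0.995) were lost, and GATA (0.071), MEF2 (-0.96) and NFY (-0.0039) turned. Without widening AP-1 was lost (0.43), NFY turned and passed (-0.64), and PU.1 passed (-2.11). With footprints shared by both libraries AP-1 was lost (0.37), GATA passed (-0.44), and MEF2 (-0.57) and SRF (0.056) turned. In each alternative that gave GATA a call, it lay below the windows.

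Leaving out each replicate gave a range of 1 to 5 peaks upstream of Hbb-y. Open promoters ranged from 2 to 3 for beta-globin, 0 to 1 for cholangiocyte, 4 to 10 for hepatoblast and 2 to 3 for megakaryocyte genes. Distal peaks per gene ranged from 5.4 to 6.4 for alpha-globin, 1.0 to 4.6 for beta-globin, 1.0 to 2.06 for hepatoblast, 4.0 to 4.25 for housekeeping, 1.8 to 2.0 for megakaryocyte and 1.8 to 1.9 for muscle genes. Peaks of replicate 1 alone need not be shared, so these counts can only be as high or higher. With replicate 1 alone, means over 1.5 times those printed, with no change of call, were 7.75 for erythroid regulators, 5.32 for erythroid membrane and heme, 4.64 for progenitor, 1.21 for mature hepatocyte, 2.77 for myeloid, 1.8 for endothelial, 1.64 for stellate, 1.5 for cholangiocyte and 2.75 for neuronal genes, and neuronal promoters numbered 5. Without the gene with the most distal peaks, no list changed its direction or its call. Mean log2 odds ratios ranged from 1.42 to 2.13 for CEBP, -0.20 to 0.062 for GATA, 0.48 to 1.29 for GATA-E-box, -0.59 to 0.74 for MEF2, -0.038 to 0.27 for NFY and -0.70 to 0.51 for SRF. Of these, hepatoblast and megakaryocyte promoters lost their call with replicate 1 alone, as did alpha-globin and housekeeping distal peaks. Megakaryocyte and cholangiocyte promoters lost it with replicate 2 alone. CEBP, NFY and, below 0, GATA passed with replicate 2 alone, and GATA-E-box with replicate 1 alone. Peaks in 1 library only had median values of 0.653 and 0.596; whether depth limits them was not tested.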

Other observations

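The tests of GC content and of GATA peaks near erythroid genes were set before their results were seen; the other tests below, and the choice of the patterns, came only after.

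Sites matched by different motif patterns had different median ratios. The excess log2 ratio was here taken among distal shared peaks and read for those in the upper 50% of replicate 1 values, where peaks without a given motif lay between -0.10 and 0.01. Peaks with a CTCF match had a median of 0.07 ± 0.012 (SE, 1298 peaks) against -0.10 without, and 8.45% of the distal CTCF peaks in the upper 50% of replicate 1 values had no peak in replicate 2, where 15.8% was expected from height. Those with a GATA match had -0.19 ± 0.010 (2755 peaks) against 0.0055, with a KLF match -0.17 ± 0.013 (1818 peaks) against -0.03, and with a GATA-E-box match -0.34 ± 0.026 (362 peaks) against -0.05. Peaks with SP (-0.17 ± 0.029), RUNX (-0.16 ± 0.026), NFE2 (-0.15 ± 0.043) and AP-1 matches (-0.12 ± 0.022) were also low, each against -0.06 without. By their patterns, each SP match holds a KLF match and each NFE2 match an AP-1 match. Peaks that also had a GATA or KLF match were not set apart. Whether the low ratio was particular to GATA and KLF was thus not tested. The SE is over peaks, which are not independent replicates. Erythroid promoters called in both libraries went both ways: Gata1 had -0.84 and Trim10 -0.72, and Rhag and Lmo2 had 0.44 each. These genes were named after their values were seen.

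The peak in an intron of Nprl3 from 32250941 to 32251160, chosen after its value was seen, had 5.41 in replicate 1 and not a base with a listed false discovery rate in replicate 2. It was the only 1 of 8949 peaks of replicate 1 with a value of at least 4 for which this held, against 16 of 11332 at 3 or more and 14194 of all 47198. In the other direction it held for 0 of 5455 peaks of replicate 2 with a value of at least 4. Replicate 2 had peaks called down to 0.0970 over the genome and to 1.79 at this locus.

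The first pattern is the beta-globin locus, whose 4 shared peaks had a median excess log2 ratio of -0.78 (from -1.42 to -0.71). The 9 shared alpha-globin peaks ranged from -1.03 to 0.66. Those at the starts of Mpg, Hbq1a, Hbq1b and Nprl3 had 0.009, 0.10, 0.26 and 0.66. The other shared alpha-globin peaks, away from starts, all lay below 0, from -0.19 to -1.03. At the beta-globin locus the peaks at the starts of Hbb-bt and Hbb-bs had -0.79 and -0.71. Peaks called in 1 library only have no ratio and are left out at both loci. In replicate 1 the beta-globin locus had 9 peaks and the alpha-globin locus 11. The Nprl3 intron peak of 5.41 is among those left out. Weaker enrichment in replicate 2 as a whole is argued against as the whole cause, since 33 of 26624 runs of 4 neighbouring shared peaks (0.124%) were as low, 17 on X or Y and 16 on autosomes, the beta-globin run itself included. A lower share of erythroid cells in replicate 2 cannot be told apart from a local difference: erythroid membrane and heme promoters lay -0.21 ± 0.16 (SE) from housekeeping promoters, within 2 SE of the bound of -0.39. Regulator promoters had a median excess of -0.01 against 0.13 for housekeeping promoters, while distal peaks went the other way, with -0.02 near erythroid membrane and heme genes and -0.07 near regulators against -0.17 near housekeeping genes; nearby distal peaks need not be erythroid, so these do not decide it. A different genotype of the 2 biosamples at this locus may also account for it and stays open, because no genotype is given per biosample and the alpha-globin median of -0.19 alone does not decide it.

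The second pattern is the distal GATA-E-box peaks, of which 82.3% lay below peaks of like height against 54.4% of the other distal peaks in the upper 50% of replicate 1 values. GC content is argued against, since matching on it as well as on height left the median at -0.34 ± 0.026, where distal peaks without the match had -0.05 at like height. A lower share of erythroid cells is a candidate explanation that stays open: GATA peaks within 50000 bases of erythroid genes (49 peaks) lay -0.038 ± 0.077 from the other 2706, too few to decide. A biological difference between the biosamples was not tested, since the labels give none.

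The third pattern is the sex chromosomes. The median excess log2 ratio was -0.25 over 698 X peaks, below all 19 autosomes (-0.02 to 0.03), and it was 1.56 for the 3 Y promoters called in both libraries. All 3 were higher in replicate 2, as were 9.27% of all 11569 promoters open in both. That share covers promoters of all heights. Shared peaks with replicate 1 values of 0.160 to 0.727, where the 3 lie, had a median log2 ratio of 0.04. A higher value in replicate 2 was thus not rare at this height. Among 13 shared Y peaks (median excess -0.08), the 4 from 1010221 to 1286740 had an excess of 0.87 to 1.63. The 9 from 90718561 to 90744680 had -1.41 to 0.28. Weaker enrichment in replicate 2 as a whole is argued against for the X peaks, whose -0.25 ± 0.021 (SE) lies outside the autosomal range, but stays open for the Y promoters, which are few and in the lowest decile of values in replicate 1. A lower share of female cells in replicate 2 is consistent with the X value of -0.25, with the Xist start called in replicate 1 alone and with 1089 and 125 listed bases around it, but sex was not collected, so this remains a hypothesis.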
